A study of Zea mays with 12 samples.

How the data were processed

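RNA was measured by sequencing in leaves of maize seedlings aged 7 days. The seedlings were the wild type B73 and the mutant zmuvr8-1, named for the UV-B photoreceptor UVR8, and grew in low white light. Each genotype was sampled with and without 1 h of UV-B, with 3 libraries in each of the 4 groups and 12 libraries in all. Nothing in the sources used here says whether the replicates came from separate plants or cultures, so every p-value measures the spread between these samples.

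The deposited files hold 1 value per transcript and library, rounded to 2 decimals, and name no unit. The authors' values were read as FPKM (fragments scaled by transcript length and library size). That reading was inferred from the values, which are not whole numbers and whose sums differ between libraries, and from the authors' use of Cufflinks, which writes FPKM. Per the labels, the authors' tools were Trimmomatic 0.36, HISAT2 2.2.1.0, TopHat, Bowtie2, Cufflinks and DESeq 1.18.0 with the genome build B73 RefGen_v4, and the libraries were made with an Illumina TruSeq kit. The role and order of these tools, the strand setting and the filter on transcripts are not given in the sources used here. The same 73928 transcripts of 24905 genes were listed in every library. All of them were above 0 in zmuvr8-1 white replicate 3, while each of the other libraries had 11124 to 12969 of them at 0, so transcripts absent from that library were not analysed here.

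The values of a gene's transcripts were summed. A gene was tested when it reached at least 1 FPKM in at least 3 of the 12 libraries, which left 17850 genes. With a pseudocount of 1, log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3. The fit held 1 coefficient per group and no covariate, and it left 8 residual degrees of freedom. Empirical Bayes moderation used the trend and robust options, and p-values (two-sided) were adjusted by the Benjamini-Hochberg method over the genes of each comparison. A gene was called at an adjusted p under 0.05. The log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The 5 comparisons were UV-B against white light in each genotype, zmuvr8-1 against B73 in each light, and the genotype by UV-B interaction, which is the UV-B change in zmuvr8-1 minus that in B73. Tools for counts were not used, since the values are not counts. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

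A total of 36 gene lists, covering light and UV-B signalling, pigments, defence, hormones, transcription factor families and markers of leaf cell types, were fixed before the data were examined by patterns in gene names and descriptions. Each was tested with camera at a preset correlation of 0.01, adjusted over the 36 lists of a comparison, and again with an estimated correlation and with fry. A list's median change is given relative to the median of all genes tested where the list is said to lie above or at a distance from all genes, and otherwise as it is. The genes named were chosen by a rule also fixed before the data were examined. It took every tested gene named UVR8, HY5, COP1, RUP, chalcone synthase (CHS) or photolyase. It added the 8 largest rises and 8 largest falls among called genes with a description and a mean of at least 5 FPKM whose 3 libraries of one group all lay above those of the other, a condition not asked of the interaction. It also took up to 3 called members with the smallest p from each list, lists in the order of their smallest p, until about 30 genes were reached. This gave 31 genes for UV-B in B73, 30 for UV-B in zmuvr8-1, 30 for white light, 32 for the genotypes under UV-B and 30 for the interaction. Other genes are named as chosen after their values were seen. Gene descriptions came from the deposited files, since 0 of their gene identifiers were found in the reference table of symbols. No gene listed was named UVR8, so its transcript level is not reported here.

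The number of reads per library is not given, so the absolute depth is unknown and no counting interval was computed. The depth relative to zmuvr8-1 white replicate 3, estimated from the spacing of values between 0.1 and 0.6 FPKM, ranged from 0.77 to 1.04. The procedure was tested on simulated data in which 200 genes were changed. It recovered 80% of changes of log2 1 and 95% of changes of log2 2 for UV-B in B73, 76% and 98% for UV-B in zmuvr8-1, and 51% and 96% for the interaction. Of the genes called there, 1.34% to 2.78% were unchanged genes. Shifts shared by many genes of a library were not simulated, so these shares need not hold for the real libraries. The shares recovered cover only the genes that were changed and were not split by expression level. They therefore do not show how well changes of genes with low values were found.

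The alternatives planned before the data were examined were quantile normalization, a fit without trend, a weaker and a stricter filter (10 FPKM), a pseudocount of 0.1, fits to only the groups compared, a replicate term, stricter thresholds and leaving out each library. Alternatives chosen after seeing the data were scaling each library to a common sum, the transcript with the highest mean per gene, transcripts above 0 in all libraries, the organelle 16S ribosomal RNA (rrn16) as a covariate, the fit without the 2 libraries richest in rrn16, and quantile normalization of the comparison between genotypes and of the list tests.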

Results

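The data were 12 RNA sequencing libraries from leaves of maize seedlings, 3 each from the wild type B73 in white light, B73 after 1 h of UV-B, zmuvr8-1 in white light and zmuvr8-1 after 1 h of UV-B. The summed values ranged from 615317 to 744359 FPKM per library, and 16202 to 16867 genes reached 1 FPKM. Within groups, Pearson's r of the log2 values between libraries was 0.9565 to 0.9791 across genes, which are not independent replicates. The organelle transcript rrn16, a ribosomal RNA, stood apart in B73 white replicate 1 at 12895 FPKM and in B73 UV-B replicate 3 at 13955 FPKM. It was 5850 FPKM in B73 UV-B replicate 2, 4559 FPKM in zmuvr8-1 white replicate 3 and 1424 to 2312 FPKM in the other libraries. Levels below are means ± SD of 3 libraries in FPKM, and log2 changes and SE come from the limma fit.

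The first comparison asked how 1 h of UV-B changed the leaf transcripts of B73. Transcripts of UV-B signalling factors rose. HY5 (Zm00001d015743), a bZIP factor that promotes light-dependent gene expression, rose from 12.7 ± 1.7 to 118 ± 26.2 FPKM (log2 change 3.10, SE 0.19, adjusted p = 3.2e-06). RUP2 (Zm00001d014990), a WD-repeat repressor of UVR8, rose from 0.62 ± 0.0557 to 11.5 ± 5.71 FPKM (log2 change 2.83, SE 0.32, adjusted p = 0.00025). HY5-like (Zm00001d039658) rose from 13.6 ± 2.92 to 37.0 ± 4.74 FPKM (log2 change 1.39, adjusted p = 0.00018). A pair of genes for the E3 ubiquitin ligase COP1 rose, from 9.64 ± 0.552 to 27.8 ± 5.80 FPKM (Zm00001d018207, log2 change 1.42, adjusted p = 9.4e-05) and from 7.25 ± 0.0551 to 12.5 ± 1.42 FPKM (Zm00001d052138, log2 change 0.71, adjusted p = 0.003). Of the 12 tested members of the UV-B signalling list, 7 rose and 5 were not called, and adjusted over the list alone 8 rose and 1 fell. Their median lay 0.854 above that of all genes on the log2 scale (camera adjusted p = 4.4e-08, adjusted p = 0.028 with an estimated correlation).

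Genes for early light-induced proteins and some enzymes of pigment synthesis also rose in B73. Early light inducible protein2 (Zm00001d018940), a chlorophyll-binding protein made under light stress, went from 0.0867 ± 0.0473 to 36.1 ± 13.8 FPKM (log2 change 5.03, SE 0.22, adjusted p = 2.8e-07). Early light inducible protein1 (Zm00001d007827) rose from 2.83 ± 1.21 to 47.9 ± 18.5 FPKM (log2 change 3.66, adjusted p = 9.7e-05). Zeaxanthin epoxidase2 rose from 0.67 ± 0.339 to 1.81 ± 0.304 FPKM (log2 change 0.77, adjusted p = 0.048). That call was lost in 6 settings and without each B73 library in turn except UV-B replicate 1 (adjusted p up to 0.26). These were the 3 called members, also adjusted over the list alone, of the 7 tested in the list of early light-induced and photoprotection proteins. The median of that list lay 0.689 above that of all genes (camera adjusted p = 7.16e-05, adjusted p = 0.0642 with an estimated correlation). Phytoene synthase2, which makes the first carotenoid, rose from 31.7 ± 1.94 to 164 ± 13.6 FPKM (log2 change 2.34, adjusted p = 2.2e-06). Glutamyl-tRNA reductase 1, an early enzyme of chlorophyll synthesis, rose from 6.70 ± 0.999 to 34.9 ± 2.26 FPKM (log2 change 2.23, adjusted p = 2.6e-06). Geranylgeranyl pyrophosphate synthase1 rose from 22.3 ± 2.77 to 35.4 ± 3.44 FPKM (log2 change 0.64, adjusted p = 0.0034). The list of chlorophyll and carotenoid biosynthesis had 4 rises and 3 falls among 28 members, the same adjusted over the list alone, and was not called as a list (camera adjusted p = 0.235).

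Some genes of phenylpropanoid metabolism, the path to lignin and UV-absorbing phenolics, rose. Of 27 members 11 rose and 2 fell (14 and 5 adjusted over the list alone). Their median lay 0.638 above that of all genes (camera adjusted p = 4.4e-08, adjusted p = 0.0642 with an estimated correlation). Phenylalanine ammonia lyase7 (Zm00001d017279), named by the rule in zmuvr8-1, rose from 3.88 ± 0.975 to 37.7 ± 2.36 FPKM (log2 change 3, adjusted p = 2.2e-06). Phenylalanine ammonia lyase9 (Zm00001d017275) rose from 51.8 ± 7.21 to 231 ± 23.3 FPKM (log2 change 2.14, adjusted p = 3e-05). Both enzymes open the pathway. Chalcone synthase C2 (colorless2), which opens flavonoid synthesis, rose from 34.2 ± 5.29 to 55.4 ± 8.75 FPKM (log2 change 0.68, adjusted p = 0.013). This call was lost when only the B73 libraries were fitted (adjusted p = 0.054). The flavonoid biosynthesis list had 3 rises and 2 falls among 24 members, the same adjusted over the list alone, and was not called (camera adjusted p = 0.235). The DNA photolyase gene Zm00001d021295, whose product repairs UV lesions, rose from 31.1 ± 0.857 to 44.4 ± 3.47 FPKM (log2 change 0.50, adjusted p = 0.0054). Its call was lost with the transcript of highest mean (adjusted p = 0.31). The photolyase gene Zm00001d034338 stood at 53.5 ± 10.5 and 54.7 ± 15.1 FPKM (adjusted p = 0.95).

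Among the other large rises in B73 were genes of carbon, amino acid and transport functions. Phosphoenolpyruvate carboxylase kinase1, which activates the C4 carboxylase, rose from 3.81 ± 2.11 to 89.8 ± 32.0 FPKM (log2 change 4.28, adjusted p = 3.1e-05). Monooxygenase 1 rose to 31.1 ± 12.6 FPKM (log2 change 3.84) and aldehyde dehydrogenase3 from 3.86 ± 0.447 to 65.0 ± 7.70 FPKM (log2 change 3.76). Actin-1 (Zm00001d033790), a gene described as cytoskeletal actin, rose from 18.2 ± 1.38 to 250 ± 26.8 FPKM (log2 change 3.71). The transporter DETOXIFICATION 21 rose from 21.5 ± 1.10 to 276 ± 18.8 FPKM (log2 change 3.62). O-succinylhomoserine sulfhydrylase rose from 9.72 ± 3.98 to 126 ± 42.6 FPKM (log2 change 3.57). The adjusted p of these last 5 genes lay between 1.2e-07 and 3e-04.

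Several hormone and defence lists lay above the other genes in B73. The jasmonate list, with 10 rises and 2 falls among 45 members (12 and 4 adjusted over the list alone), had camera adjusted p = 0.000268, and adjusted p = 0.735 with an estimated correlation. The gibberellin and brassinosteroid list had 5 rises and 4 falls among 33 members, 6 and 4 adjusted over the list alone (camera adjusted p = 0.000512, adjusted p = 0.225 with an estimated correlation). Of 12 members of the benzoxazinoid list, defence compounds of grasses, 3 rose (4 adjusted over the list alone) and 9 were not called (camera adjusted p = 0.000241, adjusted p = 0.407 with an estimated correlation). Terpenoid phytoalexins had 1 rise and 1 fall among 7 members, the same adjusted over the list alone (camera adjusted p = 0.0456, adjusted p = 0.225 with an estimated correlation). Their call was lost with quantile-normalized values (adjusted p = 0.153). Pathogenesis-related genes had 6 rises and 2 falls among 35 members, 9 and 4 adjusted over the list alone (camera adjusted p = 0.00659, adjusted p = 0.743 with an estimated correlation). The list of ethylene response factors was called upward (camera adjusted p = 0.0329). However, its median of -0.05 and mean of -0.003 were below 0, and 11 of its 61 members fell against 8 that rose (12 and 11 adjusted over the list alone), while the median of all genes was -0.20. It had adjusted p = 0.743 with an estimated correlation and lost its call with quantile-normalized values (adjusted p = 0.111).

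Of the marker lists of cell types, those of epidermis and mesophyll were called in B73. Of 53 epidermis and cuticle markers 9 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.00659, adjusted p = 0.735 with an estimated correlation). Their median of -0.06 and mean of 0.116 differed in sign. The GDSL esterase/lipase genes Zm00001d033079, from 7.14 ± 0.5 to 54.4 ± 6.78 FPKM (log2 change 2.76, adjusted p = 1.2e-07), and Zm00001d014820, from 5.14 ± 1.39 to 23.1 ± 7.10 FPKM (log2 change 1.96, adjusted p = 0.00012), were among the rises. The gene for 3-ketoacyl-CoA synthase 12, an enzyme of wax chain elongation, fell from 2.80 ± 0.618 to 0.597 ± 0.0737 FPKM (log2 change -1.24, adjusted p = 0.00063). Of 11 mesophyll markers 2 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0456, adjusted p = 0.225 with an estimated correlation). The call was lost with quantile-normalized values (adjusted p = 0.141). By its name the list also took in phosphoenolpyruvate carboxylase kinase1, which activates the C4 carboxylase and is 1 of the 2 rises. The list was not tested without this gene, so its call need not reflect markers of mesophyll cells. Vascular, bundle sheath and root or other organ markers were not called (camera adjusted p = 0.871, 0.303 and 0.128). Of 55 organelle-encoded genes 1 rose, though not adjusted over the list alone. The list lay 0.519 above all genes (camera adjusted p = 0.000268, adjusted p = 0.743 with an estimated correlation). B73 held both libraries rich in rrn16, 1 in each light.

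Among 223 genes for cytosolic ribosomal proteins, 123 fell and 100 were not called in B73 (154 fell adjusted over the list alone). Their median lay -0.41 from that of all genes (camera adjusted p = 2.02e-11, adjusted p = 0.743 with an estimated correlation). With quantile-normalized values 92 of them fell. Of 118 markers of dividing or meristematic tissue 23 fell and 4 rose, the same adjusted over the list alone. That list was not called (camera adjusted p = 0.0864, adjusted p = 0.933 with an estimated correlation), but with quantile-normalized values it was called downward (adjusted p = 0.024). Receptor-like protein kinase 4 fell from 26.0 ± 1.96 to 4.79 ± 0.494 FPKM (log2 change -2.22, adjusted p = 1.2e-06). SAUR61, a small auxin-responsive gene, fell from 31.2 ± 0.912 to 7.98 ± 2.26 FPKM (log2 change -1.87, adjusted p = 0.00011). The SNF1-related kinase subunit beta-1, part of an energy-sensing kinase, fell from 55.7 ± 5.03 to 14.7 ± 5.41 FPKM (log2 change -1.91, adjusted p = 0.00037). Salicylate/benzoate carboxyl methyltransferase fell from 53.6 ± 24.5 to 10.6 ± 2.49 FPKM (log2 change -2.16, adjusted p = 0.0025). CASP-like protein 1D1 fell from 14.7 ± 4.15 to 2.62 ± 1.31 FPKM (log2 change -2.15, adjusted p = 0.0014). B12D protein fell from 75.3 ± 19.9 to 27 ± 20.6 FPKM (adjusted p = 0.046), a call lost in 7 settings and without each of the B73 white libraries in turn (adjusted p up to 0.13). The large subunit rRNA entry ENSRNA049462348 was listed at 1207.38, 52.83 and 128.98 FPKM in the B73 white libraries and at 0 in the 3 UV-B libraries. The spliceosomal RNA entry U2 (ENSRNA049472005) was listed at 4.38, 12.65 and 12.24 FPKM in B73 white light and at 3.51, 0 and 0 FPKM after UV-B (adjusted p = 0.022). The U2 call was lost without white replicate 2 or 3 or UV-B replicate 2 or 3 (adjusted p up to 0.086).

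In total, 3993 of 17850 genes were called between UV-B and white light in B73, of which 1066 rose and 2927 fell. The median change of all genes was -0.20 on the log2 scale, against -0.05 after quantile normalization, which centres the genes. Quantile normalization called 1602 rises and 1510 falls. Scaling to a common sum, which does not centre them, called 1274 rises and 2819 falls. The excess of falls thus depended on whether the genes were centred. Of the genes called as deposited with a fold change of at least 2, 398 rose and 272 fell. The number called was 1820 without B73 white replicate 2, 2102 without white replicate 3, 2319 without UV-B replicate 2, 2199 without UV-B replicate 3, and 1978 without both libraries rich in rrn16.

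**Figure D1:**
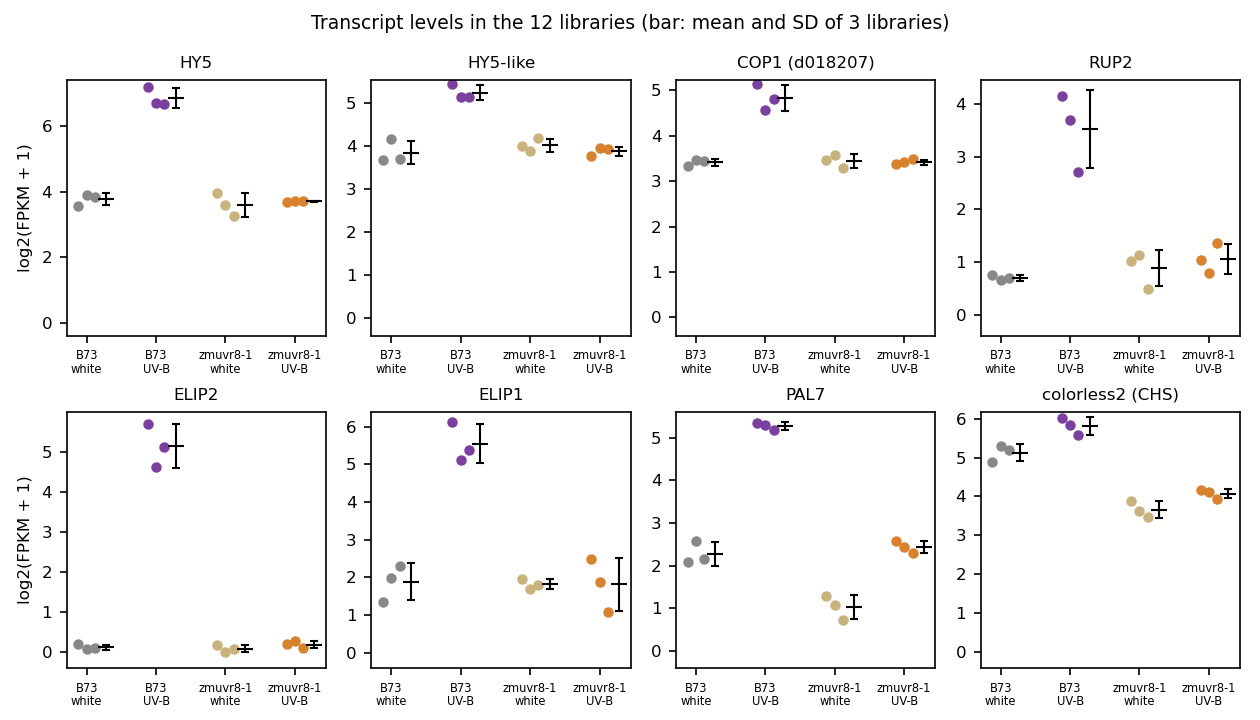
Levels of 8 UV-B response genes in log2(FPKM + 1) in the 4 groups. Points are libraries, 3 per group, and bars give the mean and SD; HY5 stood at 118 FPKM in B73 after UV-B and at 11.4 to 12.7 FPKM in the other groups.

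The second comparison asked which transcripts 1 h of UV-B changed in zmuvr8-1. Some pathogenesis-related genes rose. Hevein-like preproprotein (Zm00001d048950), a chitin-binding protein, went from 2.88 ± 0.559 to 31.8 ± 23.1 FPKM (log2 change 2.83, SE 0.42, adjusted p = 0.0078). The call was lost when only the zmuvr8-1 libraries were fitted (adjusted p = 0.058). Chitinase 1, which cuts chitin, rose from 0.543 ± 0.103 to 4.8 ± 0.423 FPKM (log2 change 1.91, adjusted p = 0.00015). Endochitinase precursor4 rose from 6.48 ± 1.35 to 22.4 ± 2.80 FPKM (log2 change 1.65, adjusted p = 0.0083), and pathogenesis related protein5 from 33.2 ± 8.28 to 145 ± 62.3 FPKM (log2 change 2.02, adjusted p = 0.0092). Of 35 pathogenesis-related genes 6 rose and 29 were not called (11 rose adjusted over the list alone). Their median lay 0.333 above that of all genes (camera adjusted p = 0.00028, adjusted p = 0.657 with an estimated correlation). The same genes in B73 are described above, and of the 4 genes just named, the interaction was called for the hevein-like gene and both chitinases but not for pathogenesis related protein5 (adjusted p = 0.12).

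The UV-B signalling genes that rose in B73 were not called in zmuvr8-1. HY5 stood at 11.4 ± 3.13 FPKM in white light and 12.1 ± 0.12 FPKM after UV-B (adjusted p = 0.82). HY5-like stood at 15.3 ± 1.67 and 13.8 ± 1.06 FPKM (adjusted p = 0.67), and RUP2 at 0.88 ± 0.416 and 1.11 ± 0.419 FPKM (adjusted p = 0.82). The COP1 genes stood at 9.87 ± 1.10 and 9.70 ± 0.407 FPKM (adjusted p = 0.96) and at 7.02 ± 1.16 and 6.40 ± 0.351 FPKM (adjusted p = 0.68). Chalcone synthase C2 was at 11.8 ± 1.91 and 15.9 ± 1.38 FPKM (adjusted p = 0.18). The photolyase genes were at 44.5 ± 2.95 and 39.2 ± 2 FPKM (Zm00001d021295, adjusted p = 0.34) and 51.5 ± 3.40 and 48.3 ± 1.29 FPKM (Zm00001d034338, adjusted p = 0.85). The UV-B signalling list was not called (camera adjusted p = 0.453).

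Some phenylpropanoid genes rose in zmuvr8-1. Of 27 members 6 rose and 21 were not called (13 rose adjusted over the list alone, and 3 with quantile-normalized values). Among them were phenylalanine ammonia lyase7, from 1.07 ± 0.392 to 4.43 ± 0.506 FPKM (log2 change 1.40, adjusted p = 0.0044), and phenylalanine ammonia lyase9, from 30.5 ± 1.69 to 64.5 ± 17.6 FPKM (log2 change 1.03, adjusted p = 0.014). Phenylalanine ammonia lyase5 rose from 8.74 ± 0.778 to 14.5 ± 1.5 FPKM (log2 change 0.67, adjusted p = 0.012). The call of the last was lost without white replicate 2 and without UV-B replicate 1 (adjusted p up to 0.055). The list had camera adjusted p = 0.000524, and adjusted p = 0.389 with an estimated correlation. Of the transcription factor lists 3 lay above other genes. Of 61 ethylene response factors 9 rose (camera adjusted p = 5.64e-05, adjusted p = 0.63 with an estimated correlation). For WRKY factors 11 of 65 rose (camera adjusted p = 0.00655) and for NAC factors 6 of 48 (camera adjusted p = 0.00457), both with adjusted p = 0.763 with an estimated correlation. Adjusted over the list alone, 18, 16 and 10 members rose. MYB factors, with 2 rises and 1 fall among 129, and B-box zinc fingers were not called as lists (camera adjusted p = 0.742 and 0.505). WRKY-transcription factor 68 rose from 1.61 ± 0.728 to 12.2 ± 3.92 FPKM (log2 change 2.33, adjusted p = 0.0083).

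Among 223 heat shock proteins and chaperones 22 rose, or 46 with 1 fall adjusted over the list alone (camera adjusted p = 0.0067, adjusted p = 0.763 with an estimated correlation). Among 38 class III peroxidases 6 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0418, adjusted p = 0.763 with an estimated correlation). Antioxidant enzymes, glutathione transferases and terpenoid phytoalexins were not called as lists (camera adjusted p = 0.784, 0.0739 and 0.336), though glutathione transferases were called upward with quantile-normalized values (adjusted p = 0.00581). Benzoxazinoid genes had 2 rises among 12, or 3 adjusted over the list alone (camera adjusted p = 0.00457, adjusted p = 0.657 with an estimated correlation). Cytosolic ribosomal protein genes had 5 rises among 223, lost adjusted over the list alone (camera adjusted p = 0.00114, adjusted p = 0.773 with an estimated correlation). Rises of O-succinylhomoserine sulfhydrylase (7.26 ± 1.86 to 48.6 ± 28.7 FPKM), terpene synthase2 (2.31 ± 1.88 to 21.5 ± 13.9 FPKM), F-box/kelch-repeat protein SKIP20, Tubulin beta-4 chain, chaperone protein dnaJ 11 and a Kelch repeat protein kinase had log2 changes of 2.23 to 2.69. That of the sulfhydrylase was lost without white replicate 2 (adjusted p = 0.054), and those of the others when only the zmuvr8-1 libraries were fitted and without white replicate 3 or UV-B replicate 1 (adjusted p up to 0.12).

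Falls in zmuvr8-1 were led by the gene for Mg chelatase subunit H 1, the chelatase of chlorophyll synthesis, from 179 ± 11 to 70.1 ± 2.87 FPKM (log2 change -1.34, SE 0.09, adjusted p = 0.00015). Alpha expansin5, a wall-loosening protein, fell from 15.1 ± 2.35 to 6.36 ± 1.34 FPKM (log2 change -1.14, adjusted p = 0.0069). Mediator subunit 33A, of the transcription machinery, fell from 88.7 ± 5.97 to 47.1 ± 3.14 FPKM (log2 change -0.90, adjusted p = 0.0044). Cytochrome c oxidase subunit 5b-2, sulfate transporter 4.1, Zea nodulation homolog1, the receptor-like kinase PERK1 and Expansin-B4 fell by log2 changes of -0.85 to -1.06. These calls were lost in at least 1 setting, and except for PERK1 also without white replicate 1, 2 or 3 or UV-B replicate 1 (adjusted p up to 0.31). The chlorophyll and carotenoid list lay -0.23 from all genes with Mg chelatase as its called member, also adjusted over the list alone (camera adjusted p = 0.00568, adjusted p = 0.494 with an estimated correlation). Light-harvesting and photosystem genes lay -0.30 from all genes (camera adjusted p = 3.34e-06, adjusted p = 0.763 with an estimated correlation). Its 2 called members of 65, both psbY genes of photosystem II, rose instead, also adjusted over the list alone. The auxin list, with 1 rise and 1 fall among 94 members, lay -0.11 from all genes (camera adjusted p = 0.00178, adjusted p = 0.389 with an estimated correlation). Organelle-encoded genes, with 1 rise among 55, lay -0.18 from all genes (camera adjusted p = 0.00928, adjusted p = 0.763 with an estimated correlation). The call of the organelle list was lost with quantile-normalized values (adjusted p = 0.21). The calls of single auxin and organelle genes were lost adjusted over the list alone.

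In total 679 genes were called in zmuvr8-1, of which 615 rose and 64 fell, with a median change of all genes of 0.088 on the log2 scale. Quantile normalization, with a median of -0.02, called 341 rises and 124 falls. The number called was 112 without UV-B replicate 1, 144 without UV-B replicate 2, 144 without white replicate 2, 253 without white replicate 3 and 300 without white replicate 1. It thus rested on each of these libraries, and it was 313 when only the zmuvr8-1 libraries were fitted.

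The interaction asked directly whether the UV-B change differed between the genotypes. For HY5 it was -3 on the log2 scale (SE 0.27, adjusted p = 2e-04) and for RUP2 -2.65 (adjusted p = 0.0057). It was -1.53 for HY5-like (adjusted p = 0.002) and -1.44 (adjusted p = 0.0019) and -0.81 (adjusted p = 0.012) for the COP1 genes, each a smaller change in zmuvr8-1. In the UV-B signalling list 7 of 12 interactions were negative and 1 was positive (the same adjusted over the list alone). The list's median lay -1.095 from that of all genes (camera adjusted p = 2.21e-08, adjusted p = 0.0243 with an estimated correlation). Early light inducible protein2, which stayed at 0.06 ± 0.06 and 0.137 ± 0.0651 FPKM in zmuvr8-1, had an interaction of -4.93 (SE 0.31, adjusted p = 1.4e-05). That of early light inducible protein1 was -3.67 (adjusted p = 0.002). The list of early light-induced proteins had 2 negative interactions among 7, or 3 adjusted over the list alone, and camera adjusted p = 1.42e-05, and adjusted p = 0.0646 with an estimated correlation. The interaction of Chalcone synthase C2 was not called (-0.27, adjusted p = 0.41), nor was that of photolyase Zm00001d034338 (-0.11, adjusted p = 0.8). That of photolyase Zm00001d021295 was -0.67 (adjusted p = 0.0098, lost with the transcript of highest mean).

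Most other large rises of B73 also had a negative interaction. It was -4.17 for monooxygenase 1 (adjusted p = 0.0015), -4.01 for phosphoenolpyruvate carboxylase kinase1 (adjusted p = 0.0013), -3.92 for Actin-1 (adjusted p = 4.5e-06), -3.68 for DETOXIFICATION 21 (adjusted p = 4.5e-06) and -3.53 for aldehyde dehydrogenase3 (adjusted p = 1.4e-05). That of O-succinylhomoserine sulfhydrylase was not called (-1.12, adjusted p = 0.2). Verprolin went from 5.85 ± 0.855 to 38.6 ± 5.43 FPKM in B73 and stood at 4.33 ± 1.53 and 2.30 ± 2.84 FPKM in zmuvr8-1 (interaction -3.58, adjusted p = 0.0099, lost with a pseudocount of 0.1). The GDSL esterase/lipase genes Zm00001d033079 (-2.59, adjusted p = 9.1e-06) and Zm00001d014820 (-1.76, adjusted p = 0.0042) and the pigment genes phytoene synthase2 (-2.48, adjusted p = 6.4e-05) and glutamyl-tRNA reductase 1 (-2.07, adjusted p = 0.00019) changed less in zmuvr8-1. Mg chelatase subunit H 1 stood at 103 ± 3.32 and 115 ± 5.28 FPKM in B73 and fell in zmuvr8-1 (interaction -1.5, adjusted p = 0.00019). The chlorophyll and carotenoid list, with 2 positive and 4 negative interactions among 28 (5 and 4 adjusted over the list alone), was called downward (camera adjusted p = 0.00262, adjusted p = 0.369 with an estimated correlation). Its median was 0.012 and its mean -0.12. Phenylpropanoid genes had 1 positive and 7 negative interactions among 27 (2 and 7 adjusted over the list alone), with a median of 0.11 and a mean of -0.28 (camera adjusted p = 0.00102, adjusted p = 0.369 with an estimated correlation).

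Genes with a positive interaction included thiamine biosynthesis2, from 96.9 ± 12.5 to 45.0 ± 9.39 FPKM in B73 and from 41.0 ± 8.69 to 125 ± 47.5 FPKM in zmuvr8-1 (interaction 2.63, adjusted p = 0.0035). Dormancy-associated protein homolog 3 went from 51.0 ± 13.4 to 16.3 ± 7.11 FPKM in B73 and from 35.6 ± 8.4 to 61.8 ± 9.41 FPKM in zmuvr8-1 (2.44, adjusted p = 0.0077). The interaction was 2.49 for indole-3-glycerol phosphate synthase, an enzyme of indole synthesis (adjusted p = 0.0014), 2.48 for salicylate/benzoate carboxyl methyltransferase (adjusted p = 0.011), and 1.06 for GDSL esterase/lipase LIP-4 (adjusted p = 0.005). The calls of 2.99 for Protein CCC1 (adjusted p = 0.029), 2.74 for the hevein-like gene (adjusted p = 0.014) and 2.51 for neomenthol dehydrogenase (adjusted p = 0.026) were lost without both libraries rich in rrn16 or with the transcript of highest mean. The first and the last were also lost without several single libraries, zmuvr8-1 white replicates 1 and 2 among them (adjusted p up to 0.1). The entries U2 (5.27, adjusted p = 0.0077) and Plant_U3 (-4.04, adjusted p = 0.04) were small RNAs listed at 0 in several libraries. In the zmuvr8-1 libraries U2 (ENSRNA049472005) was listed at 0, 0 and 2.97 FPKM in white light and 10.23, 13.97 and 5.26 FPKM after UV-B. Plant_U3 (ENSRNA049476041) was listed at 0, 5.61 and 4.85 FPKM in B73 white light, 8.15, 13.48 and 9.20 FPKM in B73 after UV-B. In zmuvr8-1 it was listed at 14.04, 5.83 and 7.31 FPKM in white light and 0, 0 and 5.70 FPKM after UV-B. The Plant_U3 call was lost in 4 settings and without 9 of the 12 libraries left out in turn (adjusted p up to 0.099). The exceptions were B73 white replicate 2, B73 UV-B replicate 1 and zmuvr8-1 UV-B replicate 3.

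Of 223 cytosolic ribosomal protein genes 110 had a positive interaction and 1 a negative one (168 and 2 adjusted over the list alone). The median lay 0.589 above that of all genes (camera adjusted p = 6.23e-13, adjusted p = 0.604 with an estimated correlation). With quantile-normalized values the counts were 66 and 1. Light-harvesting genes, with 3 negative interactions among 65, were called downward (camera adjusted p = 1.45e-05, adjusted p = 0.744 with an estimated correlation), a call lost with quantile-normalized values (adjusted p = 0.407). Cell wall loosening genes had 1 interaction in each direction among 36, and like those of the light-harvesting genes they were lost adjusted over the list alone (camera adjusted p = 0.00313, adjusted p = 0.604 with an estimated correlation). Mesophyll markers had 1 positive and 2 negative among 11, the same adjusted over the list alone (camera adjusted p = 0.0337, adjusted p = 0.295 with an estimated correlation). Their call was also lost with quantile-normalized values (adjusted p = 0.168). Phosphoenolpyruvate carboxylase kinase1, taken in by its name, is 1 of the 2 negative members, and the list was not tested without it. Organelle-encoded genes lay -0.52 from all genes (camera adjusted p = 4.2e-06, adjusted p = 0.604 with an estimated correlation). The interaction of each single member was not called, and the libraries rich in rrn16 were both of B73, 1 in each light.

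In total the interaction was called for 2720 genes, 2236 positive and 484 negative, with a median over all genes of 0.279. Quantile normalization, which centres the genes, had a median of 0.035 and called 753 positive and 810 negative. Scaling to a common sum, which does not centre them, called 2441 positive and 584 negative. The excess of positive values thus depended on whether the genes were centred. The number called was 4265 without B73 UV-B replicate 1 and between 1304 and 1799 without B73 white replicate 2 or 3, B73 UV-B replicate 2 or 3, zmuvr8-1 white replicate 2 or 3, or zmuvr8-1 UV-B replicate 2.

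Of the 1066 genes that rose in B73, 114 also rose in zmuvr8-1, against 36.7 for independent lists (exact hypergeometric test, one-sided, p = 3.36e-28, which treats genes as independent). That count rested on single libraries too, at 32 and 42 without zmuvr8-1 UV-B replicates 1 and 2, and 58, 40 and 67 without zmuvr8-1 white replicates 1, 2 and 3. It was 59 and 71 without B73 white replicates 2 and 3 and 60 without B73 UV-B replicate 2. For 434 of the 1066 (40.7%) the interaction was called, 428 of them with the smaller change in zmuvr8-1. The median change of the 1066 genes was 0.837 in B73 and 0.185 in zmuvr8-1, a ratio of 0.221, which was 0.102 with quantile-normalized values. Choosing genes by their change in B73 in itself favours a smaller change in zmuvr8-1. The 615 genes that rose in zmuvr8-1 had a median change of 0.77 there and 0.016 in B73. Of the 2927 genes that fell in B73, 19 also fell in zmuvr8-1 (10.5 for independent lists, exact hypergeometric p = 0.00566), and for 1509 (51.6%) the interaction was called. Their median change was -0.59 in B73 and 0.09 in zmuvr8-1, against -0.195 and 0.088 for all genes. Among genes with a fold change of at least 2 in B73, the interaction was called for 257 of 398 rises and 157 of 272 falls. Across the 4450 genes called in either genotype, Pearson's r of the changes was 0.247 and Spearman's rho 0.228; genes are not independent replicates. Together 1943 genes were called both in B73 and for the interaction. That count rested on single libraries, at 824 without B73 white replicate 2, 950 without B73 white replicate 3, 988 without zmuvr8-1 UV-B replicate 2, and 1015 without B73 UV-B replicate 3. It was 1162 without B73 UV-B replicate 2, 1253 without zmuvr8-1 white replicate 2, 1295 without zmuvr8-1 UV-B replicate 3 and 3252 without B73 UV-B replicate 1.

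**Figure D2:**
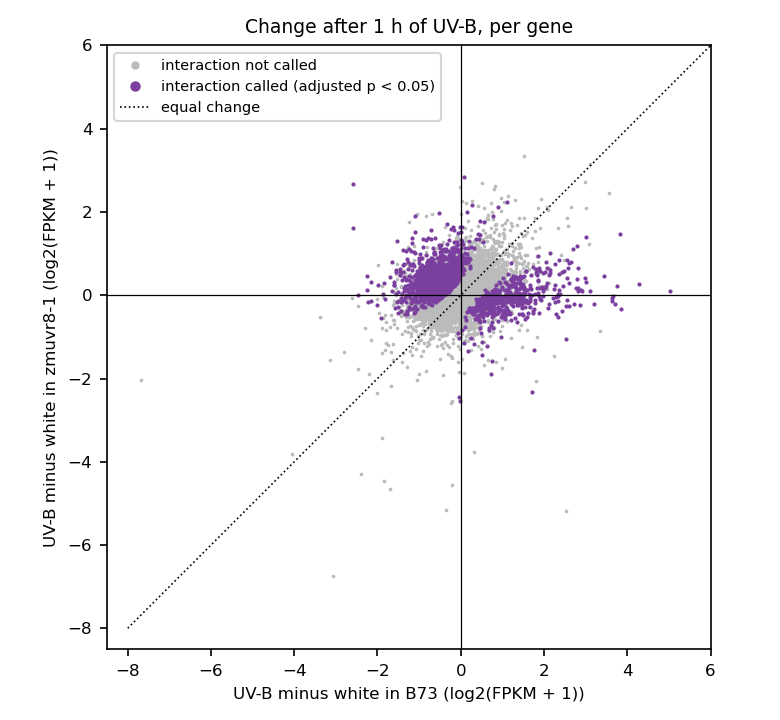
Log2 change after UV-B in B73 (x axis) and in zmuvr8-1 (y axis) for 17850 genes, on the log2(FPKM + 1) scale. Purple points are the 2720 genes whose interaction was called, and the dotted line marks an equal change in both genotypes.

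The next comparison asked how zmuvr8-1 differed from B73 in white light alone. Some genes of benzoxazinoid synthesis were lower in zmuvr8-1. Benzoxazinone synthesis11, a modifying enzyme of these grass defence compounds, was 8.80 ± 8.36 FPKM in B73 and 0.217 ± 0.196 FPKM in zmuvr8-1 (log2 difference -2.69, SE 0.49, adjusted p = 0.0089). Of 12 benzoxazinoid genes 4 were lower and 8 not called (10 lower adjusted over the list alone). Their median lay -0.80 from that of all genes (camera adjusted p = 2.97e-05, adjusted p = 0.436 with an estimated correlation). Pathogenesis-related genes, 3 lower and 1 higher among 35, and terpenoid phytoalexins were not called as lists (camera adjusted p = 0.368 and 0.117). Indole-3-glycerol phosphate synthase was lower, at 40.5 ± 2.94 FPKM in B73 and 4.89 ± 1.06 FPKM in zmuvr8-1 (log2 difference -2.83, adjusted p = 5.7e-05). Chalcone synthase C2 was lower, at 34.2 ± 5.29 and 11.8 ± 1.91 FPKM (log2 difference -1.46, adjusted p = 0.00043).

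The flavonoid list had 7 lower genes among 24, or 9 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0064, adjusted p = 0.806 with an estimated correlation). The phenylpropanoid list had 5 lower among 27, or 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00075, adjusted p = 0.436 with an estimated correlation). Lower genes also made up 9 of 36 glutathione transferases (camera adjusted p = 0.00777), 10 of 61 ethylene response factors (camera adjusted p = 0.0283), as well as 4 of 65 WRKY factors (camera adjusted p = 0.0147) and 9 of 223 cytosolic ribosomal proteins (camera adjusted p = 3.83e-06). In the jasmonate list 3 genes of 45 were lower and 1 higher (camera adjusted p = 0.0449). Each of these 5 lists had adjusted p = 0.806 with an estimated correlation. Adjusted over the list alone, 11 glutathione transferases, 14 ethylene response factors, 4 WRKY factors, 5 ribosomal proteins and 5 jasmonate genes were lower, and 2 ethylene response factors and 1 jasmonate gene were higher. Auxin genes were called upward with 4 higher among 94, the same adjusted over the list alone (camera adjusted p = 0.00168, adjusted p = 0.436 with an estimated correlation). So were cell wall loosening genes with 7 higher and 4 lower among 36, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.0449, adjusted p = 0.806 with an estimated correlation). Ethylene-responsive transcription factor 4 was lower in zmuvr8-1, at 5.96 ± 0.671 FPKM in B73 and 1.02 ± 0.121 FPKM in zmuvr8-1 (log2 difference -1.78, adjusted p = 0.00015). AP2-EREBP-transcription factor 54 (-1.94, adjusted p = 0.0012) and RAP2-3 (-1.34, adjusted p = 0.01) were lower too, the latter not without B73 white replicate 2 (adjusted p = 0.051). Of the calcium signalling genes, touch-induced calmodulin protein 2 (-2.13, adjusted p = 0.00024) and a calmodulin-like protein (-1.74, adjusted p = 0.0043) were lower and calcium-dependent protein kinase 6 higher (0.95, adjusted p = 0.00055).

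Large single differences in white light reached genes near 0 in one genotype. Every listed transcript was above 0 in zmuvr8-1 white replicate 3. A gene at 0 in all zmuvr8-1 white libraries could thus not appear, while one at 0 in all B73 white libraries could. The counts of higher and lower genes below share this limit. The gene for isochorismatase family protein rutB (Zm00001d015986) was listed at 0 in all 3 B73 white libraries and at 30.6 ± 4.04 FPKM in zmuvr8-1 (adjusted p = 2.5e-09). Metal transporter Nramp6 was 61.2 ± 15.1 FPKM in B73 and 0.06 ± 0.104 FPKM in zmuvr8-1 (log2 difference -5.85, adjusted p = 0.00013). Methylesterase 3 was 20 ± 13.0 and 0.117 ± 0.107 FPKM (-3.96, adjusted p = 0.0026). Also lower in zmuvr8-1 were neomenthol dehydrogenase (-3.63, adjusted p = 0.001), cytochrome P450 11 (-3.28, adjusted p = 0.00024) and the xylan glucuronosyltransferase Zm00001d027938 of the cell wall (-2.62, adjusted p = 0.00024). U2 (-2.65, adjusted p = 0.042) was not called in 7 settings (adjusted p up to 0.16). Higher in zmuvr8-1 were 4 genes for Glutaredoxin-C13, a redox protein, by 2.06 to 3.56 (adjusted p = 0.00081 to 0.013). That of Zm00001d040836 was not called with a pseudocount of 0.1 or without zmuvr8-1 white replicate 2 (adjusted p up to 0.12). Methylsterol monooxygenase 1-2, of sterol synthesis, was 4.34 ± 0.45 and 51.2 ± 19.3 FPKM (3.23, adjusted p = 0.00025). Asparagine synthetase3 was 1.31 ± 0.453 and 19.6 ± 11.1 FPKM (3.05, adjusted p = 0.00083), and diaminopimelate epimerase, of lysine synthesis, 1.25 ± 0.221 and 14.0 ± 1.06 FPKM (2.74, adjusted p = 4.2e-06).

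HY5, HY5-like, RUP2 and both COP1 genes were not called between genotypes in white light (adjusted p = 0.58 to 0.95), nor was photolyase Zm00001d034338 (adjusted p = 0.95). Photolyase Zm00001d021295 was higher in zmuvr8-1 (log2 difference 0.50, adjusted p = 0.0097, lost with the transcript of highest mean). In total 1179 genes were called, 415 higher and 764 lower in zmuvr8-1, against 660 higher and 750 lower with quantile-normalized values. The number was 525 without zmuvr8-1 white replicate 2, 542 without B73 white replicate 2, 545 without B73 white replicate 3 and 657 without zmuvr8-1 white replicate 1.

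The last comparison asked how the genotypes differed after 1 h of UV-B. HY5 was lower in zmuvr8-1, at 12.1 ± 0.12 against 118 ± 26.2 FPKM in B73 (log2 difference -3.16, SE 0.19, adjusted p = 2.3e-06). Also lower were RUP2 (-2.46, adjusted p = 4e-04), HY5-like (-1.36, adjusted p = 0.00015) and the COP1 genes (-1.41, adjusted p = 7.4e-05, and -0.87, adjusted p = 6e-04). In the UV-B signalling list 7 of 12 genes were lower, or 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 5.41e-07, adjusted p = 0.05 with an estimated correlation, not under the threshold before rounding). Chalcone synthase C2 was 55.4 ± 8.75 FPKM in B73 and 15.9 ± 1.38 FPKM in zmuvr8-1 (-1.73, adjusted p = 5.3e-05). The photolyases were not called (Zm00001d021295 -0.17, adjusted p = 0.18; Zm00001d034338 -0.14, adjusted p = 0.57), though each was called lower in 1 alternative.

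Phenylpropanoid genes were lower, 13 of 27 against 3 higher (14 and 3 adjusted over the list alone; camera adjusted p = 7.65e-08, adjusted p = 0.0877 with an estimated correlation). The differences were, for phenylalanine ammonia lyase7, -2.84 (adjusted p = 2.3e-06), for trans-cinnamate 4-monooxygenase, the next enzyme of the path, -2.73 (adjusted p = 1.1e-05) and for phenylalanine ammonia lyase9 -1.85 (adjusted p = 6.2e-05). Early light inducible protein2 (-4.96, adjusted p = 2.3e-07), early light inducible protein1 (-3.73, adjusted p = 6.9e-05) and photosystem II subunit PsbS1 (-0.61, adjusted p = 0.034, lost with a replicate block, when only the UV-B groups were fitted, and without each UV-B library in turn except B73 replicate 3, with adjusted p up to 0.096) were lower. They were the 3 lower genes, also adjusted over the list alone, of their list of 7 (camera adjusted p = 0.000737, adjusted p = 0.159 with an estimated correlation). Pigment genes had 8 lower and 6 higher among 28 (9 and 6 adjusted over the list alone; camera adjusted p = 0.000559, adjusted p = 0.254 with an estimated correlation). Glutamyl-tRNA reductase 1 was at -2.42 (adjusted p = 1.1e-06), phytoene synthase2 at -2.16 (adjusted p = 2.4e-06) and Mg chelatase subunit H 1 at -0.71 (adjusted p = 0.00047).

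Benzoxazinoid genes were lower in 6 of 12 cases, the same adjusted over the list alone (camera adjusted p = 7.97e-06, adjusted p = 0.275 with an estimated correlation). Jasmonate genes had 10 lower and 5 higher among 45 (camera adjusted p = 5.71e-05) and flavonoid genes 5 lower and 2 higher among 24 (camera adjusted p = 0.00163), both with adjusted p = 0.547 with an estimated correlation. Adjusted over the list alone, these counts were 10 and 5 for jasmonate and 4 and 1 for flavonoid genes. Light-harvesting genes had 6 lower and 1 higher among 65, or 2 lower adjusted over the list alone (camera adjusted p = 0.000136, adjusted p = 0.787 with an estimated correlation). Terpenoid phytoalexins had 1 lower among 7, the same adjusted over the list alone (camera adjusted p = 0.0325, adjusted p = 0.254 with an estimated correlation). Both calls were lost with quantile-normalized values (adjusted p = 0.285 and 0.129). Organelle-encoded genes had 2 lower among 55, lost adjusted over the list alone (camera adjusted p = 2.23e-07, adjusted p = 0.547 with an estimated correlation), with rrn16 at 13955 and 5850 FPKM in B73 UV-B replicates 3 and 2. Cytosolic ribosomal protein genes were higher in 146 of 223 cases, 67 with quantile-normalized values and 167 with 1 lower adjusted over the list alone (camera adjusted p = 2.23e-07, adjusted p = 0.787 with an estimated correlation). Of 118 markers of dividing or meristematic tissue 42 were higher and 2 lower, the same adjusted over the list alone. That list was not called (camera adjusted p = 0.0943, adjusted p = 0.902 with an estimated correlation), but with quantile-normalized values it was called upward (adjusted p = 0.0175).

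Among single genes, DETOXIFICATION 21 (-4.14, adjusted p = 1.2e-08), monooxygenase 1 (-4.05, adjusted p = 6.2e-05), aldehyde dehydrogenase3 (-4.02, adjusted p = 1e-07) and an AMP-dependent synthetase (-4.01, adjusted p = 1.1e-06) were lower in zmuvr8-1. The gene for rutB was 0.0633 ± 0.0709 FPKM in B73 and 29.5 ± 3.89 FPKM in zmuvr8-1 (4.83, adjusted p = 3.4e-09). Nramp6 (-4.12, adjusted p = 0.00026), asparagine synthetase3 (3.28, adjusted p = 0.00016), diaminopimelate epimerase (3.05, adjusted p = 6.3e-07) and the Glutaredoxin-C13 genes Zm00001d040836 (3.10, adjusted p = 0.0029) and Zm00001d040837 (2.84, adjusted p = 0.00068) differed the same way as in white light. Cytochrome P450 71A26 was higher (3.29, adjusted p = 0.00042). So was the glycine-rich cell wall protein Zm00001d017032 (3.37, adjusted p = 0.031), but not without any 1 of the zmuvr8-1 UV-B libraries (adjusted p up to 0.12). Of the noncoding entries, the large subunit rRNA ENSRNA049462348 was listed at 0 in the B73 UV-B libraries and at 75.29, 42.13 and 7.19 FPKM in zmuvr8-1. The small subunit rRNA ENSRNA049456552 was listed at 254, 621.76 and 1524.56 FPKM in B73 and at 0 in zmuvr8-1, and SNORD14 (ENSRNA049458782) at 67.84, 119.39 and 65.22 FPKM in B73 and at 0 in zmuvr8-1.

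In total 6160 genes were called between genotypes after UV-B, 4976 higher and 1184 lower in zmuvr8-1, with a median over all genes of 0.243. Quantile normalization, with a median of 0.042, called 2121 higher and 1867 lower. The number was 3735 without B73 UV-B replicate 3, 3750 without zmuvr8-1 UV-B replicate 2, 4049 without zmuvr8-1 UV-B replicate 3 and 4048 without both libraries rich in rrn16. Over all comparisons 56 list tests were called, and 2 of them held with an estimated correlation, those of UV-B signalling in B73 and in the interaction.

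**Figure D3:**
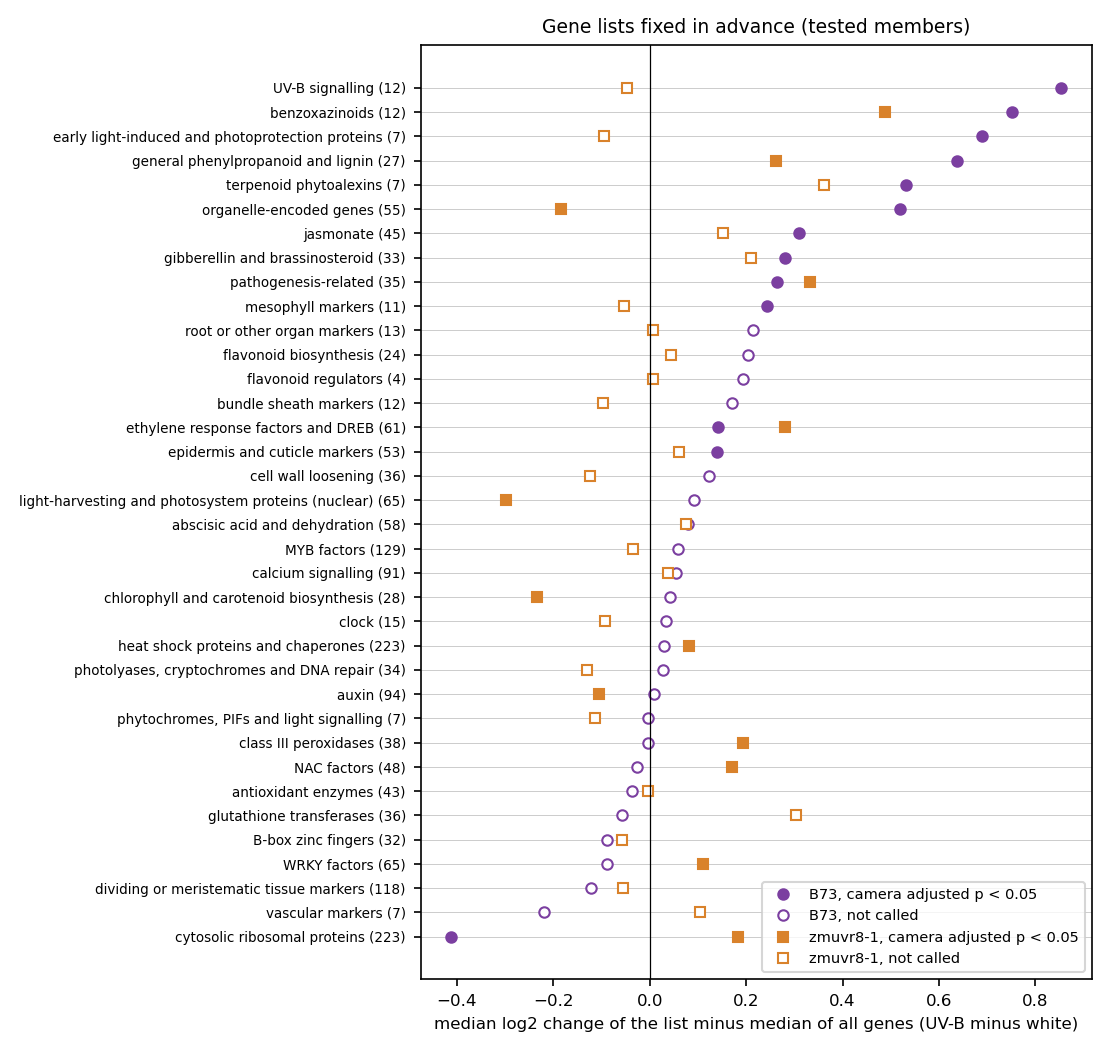
Median log2 change after UV-B of the 36 gene lists minus the median of all genes, in B73 (circles) and zmuvr8-1 (squares); filled symbols had a camera adjusted p under 0.05 at the preset correlation. The UV-B signalling list lay at 0.854 in B73.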

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

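The tests of technical explanations below were chosen after the results were seen, while the relabellings of the libraries were planned before the data were examined, except those with the effects of light and genotype removed.

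A UV-B effect that differed between the genotypes was found by the interaction test for 2720 genes. The planned relabellings of the light treatment within genotypes (1 of 100, the real one, called as many, highest of the others 1775) also remove the UV-B effect itself, so they do not test the interaction alone. With the effects of light and genotype removed first, 2 of 100 relabellings, the real one included, called as many (highest of the others 3832). The real interaction stayed in those values and widened the spread within the other relabelled groups, which lowers their counts. The share therefore cannot exclude chance. The other relabelling that called as many was put among the 100 after the counts of all 200 possible ones were seen. It set the 3 B73 libraries richest in rrn16 against the other 3 and swapped the light labels in zmuvr8-1. Of the 10 relabellings with that grouping of B73, this one and one with 2636 genes stood out and 8 called at most 14, while apart from the real one those without it called at most 1. With rrn16 as a covariate the interaction was called for 4475 genes and without the 2 libraries richest in rrn16 for 1853. In 100 simulations without an interaction, 1 reached the 1943 genes called both in B73 and for the interaction, with 2290. The interactions on the log2 scale follow, with negative values for a lower change in zmuvr8-1. Light signalling genes had -3 for HY5, -2.65 for RUP2, -1.53 for HY5-like, -1.44 and -0.81 for the COP1 genes and -0.67 for photolyase Zm00001d021295. Photoprotection and pigment genes had -4.93 for early light inducible protein2, -3.67 for early light inducible protein1, -2.48 for phytoene synthase2, -2.07 for glutamyl-tRNA reductase 1, -1.5 for Mg chelatase subunit H 1 and -0.60 for geranylgeranyl pyrophosphate synthase1. Phenylpropanoid genes had -1.60 for phenylalanine ammonia lyase7 and -1.11 for phenylalanine ammonia lyase9. Other genes with a large rise in B73 had -4.17 for monooxygenase 1, -4.01 for phosphoenolpyruvate carboxylase kinase1, -3.92 for Actin-1, -3.68 for DETOXIFICATION 21, -3.58 for Verprolin, -3.53 for aldehyde dehydrogenase3, and -2.59 and -1.76 for the GDSL esterase/lipases Zm00001d033079 and Zm00001d014820. Mediator subunit 33A had -0.83 and Plant_U3 -4.04, the latter not called in 4 settings or without 9 of the 12 libraries left out in turn (adjusted p up to 0.099).

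Positive values were 5.27 for U2, 2.99 for Protein CCC1, 2.74 for the hevein-like gene, 2.63 for thiamine biosynthesis2, 2.51 for neomenthol dehydrogenase, 2.49 for indole-3-glycerol phosphate synthase, 2.48 for salicylate/benzoate carboxyl methyltransferase, 2.44 for dormancy-associated protein homolog 3, 2.05 for receptor-like protein kinase 4 and 2.01 for CASP-like protein 1D1. They were 1.90 for SAUR61, 1.61 for endochitinase precursor4, 1.35 for the SNF1-related kinase subunit beta-1, 1.23 for 3-ketoacyl-CoA synthase 12, 1.13 for Chitinase 1 and 1.06 for GDSL esterase/lipase LIP-4. Genes chosen after their values were seen had -2.76, -2.34 and -1.21 for gibberellin 2-oxidases 2, 3 and 7, 0.80 for gibberellin 20-oxidase1, -2.24 for brassinosteroid-deficient dwarf1, -2.41 for CONSTANS-LIKE 5, 1.59 for double B-box zinc finger protein2, -1.46 for B-box zinc finger protein 22, -1.43 and -0.82 for the SPA1-related 3 genes, -1.16 for flavanone 3-hydroxylase1, 0.74 for phosphoenolpyruvate carboxylase3, -1.71 for trans-cinnamate 4-monooxygenase and -1.43 for lipoxygenase13. The calls of gibberellin 2-oxidase7 and gibberellin 20-oxidase1 were lost with quantile-normalized values, in 3 or more other settings and without most single libraries (adjusted p up to 0.11), and that of gibberellin 2-oxidase3 with a pseudocount of 0.1 and at 10 FPKM (adjusted p up to 0.1). The call of phosphoenolpyruvate carboxylase3 was lost with quantile-normalized values and with the transcript of highest mean (adjusted p up to 0.36). That of flavanone 3-hydroxylase1 was lost without both libraries rich in rrn16 and without B73 white replicate 2 (adjusted p up to 0.058). The median interactions of lists with a called test, not taken relative to the median of 0.279 over all genes, were -0.816 for UV-B signalling, -0.446 for early light-induced proteins, -0.243 for organelle-encoded genes, -0.09 for mesophyll markers, -0.084 for cell wall loosening, -0.041 for light-harvesting, 0.012 for chlorophyll and carotenoid biosynthesis, 0.11 for phenylpropanoid genes and 0.868 for cytosolic ribosomal proteins, the last alone above that of all genes.

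More genes fell than rose under UV-B in B73. Leaving out the 2 libraries rich in organelle ribosomal RNA left 29.6% of called genes rising, so those libraries were not the whole cause. However, rrn16 stayed uneven between the lights, at 5850 FPKM in UV-B replicate 2 against 1424 and 2113 FPKM in the white libraries left. With rrn16 as a covariate 25.6% of called genes rose. The authors' normalization cannot be told apart from a shift of many genes, because quantile normalization, which centres the genes, gave 51.5% rises while scaling each library to the same sum gave 31.1%. The 10 splits of the 6 B73 libraries are too few for a share under 0.05 (3993 genes in the real split, at most 1324 in the others). The split with 1324 genes set the 3 B73 libraries richest in rrn16 against the other 3. A shift of many transcripts under UV-B in B73 stays open as a biological explanation that was not tested.

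In zmuvr8-1, UV-B was followed by 615 rises. Quantile normalization still called 341, more than its falls, which argues against the normalization as the whole cause. Over transcripts above 0 in all libraries 92.9% of the called genes rose, so the rises did not need transcripts at 0 in some libraries. Those transcripts are part of the same list, however, so the effect of transcripts left out of it stays untested. Other values argue against a remainder of the B73 response as the whole cause. Of the 341 rises, 27 fell in B73 (86 of the 615). A positive interaction was called for 117 (339), and the 27 (86) were all among them, so the 2 counts are not separate checks. For genes that fell in B73, a positive interaction does not show a change of larger size in zmuvr8-1. These counts were more than 5% of the rises and of the called interactions in both scalings. As deposited, they were 6 to 138 and 61 to 473 without single libraries. Of the 2 counts, 1 was under its 5% without zmuvr8-1 white replicate 2, at 64, UV-B replicate 1, at 61, or UV-B replicate 2, at 6. The argument thus rests on those libraries, and on error shares that shifts common to a library can raise. For the other rises a remainder cannot be told apart from a separate response, since setting apart the genes above favours rises shared with B73. Those were 39.1% of the others against 6% of all genes, or 50.4% against 9% with quantile-normalized values. The 10 splits of the 6 zmuvr8-1 libraries are too few for a share under 0.05 (679 genes in the real split, at most 0 in the others at the same threshold in limma). A UV-B response of zmuvr8-1 without UVR8 may also remain, a hypothesis that was not tested.

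Between the genotypes in white light 1179 genes differed. Of the 2 libraries rich in organelle ribosomal RNA, B73 white replicate 1 alone was in this comparison. Without it 840 genes were called, and 958 without both, which argues against that library as the whole cause. Of 154 genes that differed in both lights by more than log2 1, 35.7% had another such gene within 20 genes in identifier order. That share was 29.2% on average in 1000 shuffles (permutation p = 0.09). Most of these genes thus did not lie close together. The test covers only where genes lie, so it cannot exclude a chromosome segment from another strain that acts on genes elsewhere. Several small segments stay possible too. The 10 splits of the 6 white light libraries are too few for a share under 0.05 (1179 genes in the real split, at most 3 in the others), as are those of the 6 UV-B libraries (6160 genes, at most 0 in the others at the same threshold in limma). An effect of the mutation in low white light stays open and was not tested apart from other differences between the lines.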

How the results depend on the processing

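The scaling to a common sum, the transcript choices, both rrn16 alternatives and the quantile values of the genotype comparison and of the lists were chosen after seeing the data; the other alternatives were planned. Of the comparison values recomputed, 120 were the same, 64 lower, 6 higher, 4 reversed and 1 moved. A count was the same when it stayed within 1.5 times with the same majority. The values also include ratios of medians, which are not counts and have no majority, so the 120 are not all stable counts. Without single libraries the ratio over the B73 rises ran from 0.15 to 0.279, against 0.221 with all, and each was labelled the same. Of gene calls 3382 were the same, 237 lost, 2 gained and 1 reversed, and of list calls 185 were the same and 95 lost. Below, counts are in the order UV-B in B73, UV-B in zmuvr8-1, genotypes in white light, genotypes under UV-B, interaction, and only those that changed are given. The cause was not tested except where fewer genes, fewer libraries or a stricter threshold are the cause by construction.

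Quantile normalization gave 3112 genes in B73 (1602 up, 1510 down, with the majority reversed), 3988 between genotypes under UV-B, and 1563 for the interaction (753 positive, 810 negative, reversed). It gave 1218 genes called both in B73 and for the interaction, a ratio of medians of 0.102 over the B73 rises, and one of 0.006 in place of -0.153 over the B73 falls, a reversed sign. The fold threshold of 2 left 670 (398 up, 272 down, reversed), 197, 359, 1024 and 939 genes, and adjusted p under 0.01 left 1228, 88, 399, 2593 and 612. With rrn16 as a covariate 6049, 1725, 2637 (white light) and 4475 (interaction) genes were called. Without the 2 libraries richest in rrn16 there were 1978 genes in B73, 4048 between genotypes under UV-B, 1066 in B73 and the interaction, and 62 rises in both genotypes. Fits to only the groups compared called 1608, 313 and, under UV-B, 4093 genes. The filter at 10 FPKM left 734 genes in white light and 3997 under UV-B. A replicate block, for which replicate numbers gave little support (4 of 18 pairs with the same number correlated above 0.1, range -0.411 to 0.256), gave 279 genes for zmuvr8-1, 741 in white light, 1746 for the interaction, 1229 in B73 and the interaction, and 60 rises in both genotypes.

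Leaving out each library in turn gave 1820 to 5404 genes in B73, 112 to 521 in zmuvr8-1, 525 to 1052 in white light, 3735 to 7038 under UV-B, 1304 to 4265 for the interaction, 824 to 3252 in B73 and the interaction, and 32 to 125 rises in both genotypes. That last count, 114 with all libraries, was 32 and 42 without zmuvr8-1 UV-B replicates 1 and 2, 58, 40 and 67 without zmuvr8-1 white replicates 1, 2 and 3, 59 and 71 without B73 white replicates 2 and 3, and 60 without B73 UV-B replicate 2. Of 56 list calls 2 held with an estimated correlation, 26 with fry (54 calls in total), 55 with the replicate block (55), 48 with quantile-normalized values (55) and 54 without the 2 libraries richest in rrn16 (59). Phosphoenolpyruvate carboxylase3 (Zm00001d053453) changed by -0.31 in B73, but by 0.01 with the transcript of highest mean. Calls held in every setting for 39 of 46 named genes called in B73, 9 of 24 in zmuvr8-1, 25 of 30 in white light, 26 of 30 under UV-B and 32 of 43 for the interaction. Alternatives for counts and for the UVR8 level were not run, since the values are not counts and no gene was named UVR8. The depth of the libraries is unknown, so its limit on genes with low values is too.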

Other observations

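The genes of the next paragraphs were chosen after their values were seen, by looking at members of the lists, and they were tested in the planned fits.

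The list of gibberellin and brassinosteroid genes, fixed before the data were examined, had 5 rises and 4 falls among 33 in B73 after UV-B (6 and 4 adjusted over the list alone; camera adjusted p = 0.000512, adjusted p = 0.225 with an estimated correlation). Gibberellin 2-oxidases inactivate gibberellins. Gibberellin 2-oxidase3 rose from 0.167 ± 0.11 to 15.9 ± 4.94 FPKM (log2 change 3.82, adjusted p = 9.7e-05) and gibberellin 2-oxidase7 from 0.0533 ± 0.0208 to 2.55 ± 1.21 FPKM (log2 change 1.69, adjusted p = 0.0017), while gibberellin 2-oxidase2 was listed at 0 in the 3 white light libraries and at 6.56 ± 2.24 FPKM after UV-B (adjusted p = 1.1e-05). Gibberellin 20-oxidase1, of gibberellin synthesis, fell from 9.10 ± 1.03 to 4.8 ± 1.20 FPKM (log2 change -0.82, adjusted p = 0.0067). Brassinosteroid-deficient dwarf1 was listed at 0 in white light and at 4.41 ± 2.13 FPKM after UV-B (adjusted p = 0.00045), and lipoxygenase13 rose from 0.883 ± 0.241 to 5.13 ± 1.69 FPKM (log2 change 1.67, adjusted p = 0.00056). In zmuvr8-1 the means after UV-B were 2.79 ± 2.60 FPKM for gibberellin 2-oxidase3, 0.607 ± 0.348 FPKM for gibberellin 2-oxidase7 and 13.8 ± 1.22 FPKM for gibberellin 20-oxidase1. The interactions of gibberellin 2-oxidase3 (-2.34) and gibberellin 2-oxidase7 (-1.21) were smaller in size than their changes in B73. Both estimates thus went up in zmuvr8-1 too, by less than in B73. The interaction was called for all 6 genes, but for gibberellin 2-oxidase3 not with a pseudocount of 0.1 or at 10 FPKM (adjusted p up to 0.1), and for gibberellin 2-oxidase7 and gibberellin 20-oxidase1 not without most single libraries (adjusted p up to 0.11). These last 2 calls were also lost with quantile-normalized values, a replicate block, the weaker filter and the transcript of highest mean, and that of gibberellin 2-oxidase7 with a pseudocount of 0.1.

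SPA1-related 3 genes, whose products act with COP1, rose in B73 from 14.6 ± 1.97 to 36.6 ± 3.48 FPKM (Zm00001d011746, adjusted p = 0.00055) and from 60.2 ± 5.47 to 92.2 ± 1.08 FPKM (Zm00001d043592, adjusted p = 0.0056). Of 32 B-box zinc finger genes 5 rose and 8 fell, or 5 and 10 adjusted over the list alone (camera adjusted p = 0.744). CONSTANS-LIKE 5 rose from 5.61 ± 2 to 30.4 ± 7.76 FPKM and B-box zinc finger protein 22 from 6.52 ± 1.32 to 15.5 ± 4.55 FPKM, while double B-box zinc finger protein2 fell from 5.36 ± 0.785 to 1.17 ± 0.32 FPKM (adjusted p = 0.00014, 0.0033 and 0.00044). Trans-cinnamate 4-monooxygenase rose from 38.7 ± 3.79 to 233 ± 26.8 FPKM (log2 change 2.56, adjusted p = 2.4e-05). In white light, circadian clock associated1, a morning factor of the clock, was 123 ± 14.3 FPKM in B73 and 300 ± 54.0 FPKM in zmuvr8-1 (log2 difference 1.27, adjusted p = 0.0018), and benzoxazinless1, the entry enzyme of benzoxazinoid synthesis, 197 ± 20.3 and 49.5 ± 12.9 FPKM (log2 difference -2, adjusted p = 0.0074). The clock list, with 15 tested members, was not called in white light. Mg chelatase subunit H 1 was 103 ± 3.32 FPKM in B73 and 179 ± 11 FPKM in zmuvr8-1 in white light (log2 difference 0.79, adjusted p = 0.00083).

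The first 4 principal components of the log2 values held 34.9%, 14.4%, 12.8% and 9.5% of the variance. In a simulation without any interaction, the number of genes called both in B73 and for the interaction had a median of 0 over 100 runs, and 1 run, with 2290 genes, reached the 1943 observed.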
